A study of Sorghum bicolor with 12 samples.

How the data were processed

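Whole shoots of sorghum (Sorghum bicolor), inbred line BTx623, were profiled by RNA-seq, which counts mRNA fragments, and by Ribo-seq, which counts the short mRNA fragments protected by ribosomes. Per the labels, seedlings were germinated for 5 days and then grown for 8 days with control or low-sulfate nutrient solution, so that shoots were taken 13 days after sowing. The sample titles and the growth protocol give 500 µM sulfate for the control and 10 µM for the deficient solution, whereas the design text of the series gives 0 µM for the latter. The groups are therefore called control and sulfur-deficient here. Each group had 3 shoots, described as biological replicates. Per the labels' protocols, 1 powdered shoot supplied both its RNA-seq and its Ribo-seq library, which gave 12 libraries from 6 shoots. Footprints of 26 to 34 nt were taken from a gel slice.

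The authors deposited 2 tables of raw counts per transcript, with no normalization: RNA-seq read counts for 34210 transcripts, and footprint counts, given as P sites (the codon position held by the ribosome) summed over the coding sequence, for 34026 transcripts. The deposited footprint table also lists a coding length per transcript. All of its transcripts were in the RNA table, and the 184 transcripts listed there alone held 0.0328% of the RNA counts. Bowtie2 and STAR are named in the submitters' processing notes without roles or versions. The counting program, the genome build, the annotation and the P-site offsets are not given in the sources used here. It is likewise not given how reads matching several transcripts were counted, so transcripts with near-identical copies are uncertain. Both tables use the same column names, and each table's assay was taken from its content.

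Total counts ranged from 13995665 to 18475153 per RNA library and from 6328659 to 11066815 per footprint library. Chi-square statistics per degree of freedom between libraries of a group ran from 2.7 to 18.8, all above sampling noise, and each library was counted as a separate sample.

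Changes were tested with edgeR 4.0.16 in R 4.3.3. Counts were scaled by TMM factors, transcripts were kept by filterByExpr with its minimum count of 10 and minimum total count of 15, and the robust quasi-likelihood test was applied with a Benjamini-Hochberg adjusted p threshold of 0.05. RNA and footprint libraries were fitted separately, with treatment as the term. Translational efficiency, the ratio of footprints to mRNA per transcript, was tested as the interaction of assay and treatment in 1 model over all 12 libraries, for transcripts that passed the filter in both assays. Levels are given as CPM, each count relative to the TMM-scaled library size, or to the unscaled total where the transcript failed the filter. A small prior count was added for log2 CPM and for ratios per shoot, and it weighs most at low counts. Correlations of fold changes are across transcripts, which are not independent replicates, and carry no p-value.

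Whether labels pair the libraries was checked from deviations from the group means. RNA and footprint libraries of the same shoot, which the labels say share 1 powder, had correlations between 0.106 and 0.505, so the fit with the shoot as a block applies to translational efficiency. The RNA library of deficient shoot 2 correlated better with the footprints of shoot 3 (0.235) than with its own (0.106). The check of the replicate numbers across treatments is given with the alternatives.

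The tests were tried on simulated counts with 200 changed transcripts. For RNA, 43.3% of transcripts changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, with 24 false calls among 171 calls and 19837 tested (14% of calls, above the nominal 5%). The shares for footprints were 13.4%, 59.7% and 92.4%, with 9 false calls among 119 (7.56%) and 16276 tested. For translational efficiency they were 10.4%, 53.7% and 86.4%, with 9 false calls among 109 (8.26%) and 16184 tested. No variation shared by the libraries of a shoot was simulated.

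The deposited tables carry transcript IDs without gene names. None of the IDs, 0 in all, matched the reference gene table used here (assembly Sorghum_bicolor_NCBIv3). The 31 gene lists fixed on product descriptions, among them sulfate transport, sulfate assimilation, photosynthesis and cell type lists, were therefore void and no set test was run. Without descriptions the naming rule allowed at most 2 rising and 2 falling IDs per comparison, those with the largest fold change past the threshold, at an average log2 CPM of at least 2 and with no overlap between groups. One further ID completes a count of 2 and was chosen after its values were seen.

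Alternatives fixed before the data were examined were DESeq2 1.42.0, other scaling factors, other filters, a 2-fold threshold, library sizes without the 20 most abundant transcripts, a shared spread, replicate or shoot blocks, and leaving out each shoot. Chosen after seeing the data were limma 3.58.1 (voom, or the log2 ratio per shoot), a batch term from the numbers in the sample descriptions, and leaving out each of the 9 pairs of 1 control and 1 sulfur-deficient shoot. Plots were drawn with matplotlib 3.10.9.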

Results

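Sorghum shoots grown with sufficient or low sulfate were compared at the level of mRNA and of ribosome footprints, in 3 shoots per treatment and with both assays on each shoot. RNA libraries held 13995665 to 18475153 counts and footprint libraries 6328659 to 11066815. Correlations of log2 CPM were 0.9845 to 0.9926 within groups and 0.9809 to 0.9895 between groups for RNA. For footprints they were 0.9721 to 0.9879 within groups and 0.9624 to 0.9795 between groups. The groups separated on the first principal component of the RNA libraries, which held 38.4% of the variance. On the second, with 26.4%, control shoot 3 and sulfur-deficient shoot 1 scored -15.6 and -31.1, apart from the other 4 shoots at 8.59 to 17.9. The highest RNA correlation between treatments, 0.9895, was between these same shoots.

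**Figure D1:**
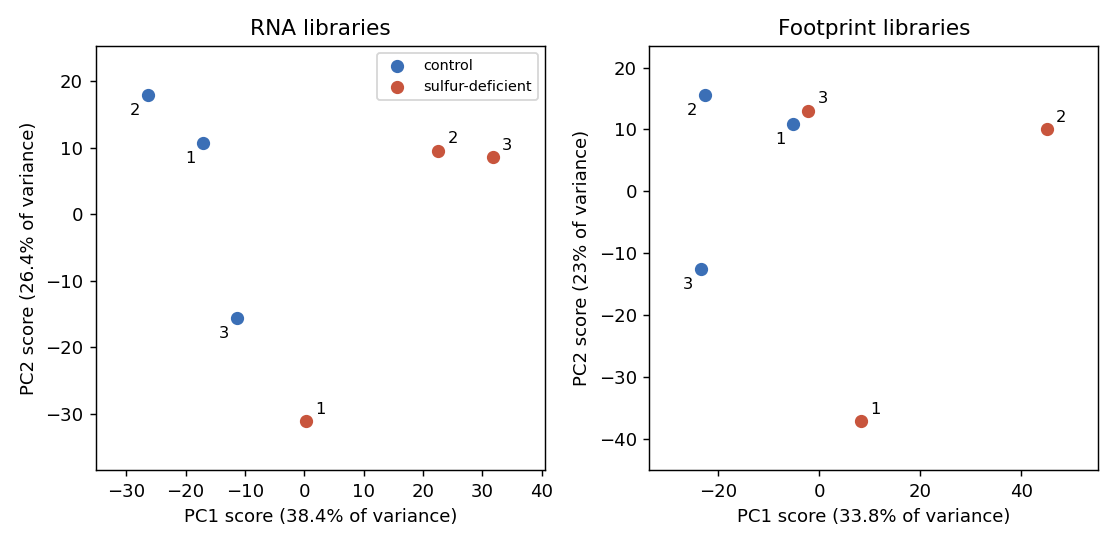
Principal component scores of log2 CPM for the 6 RNA libraries and the 6 footprint libraries, with each point a library and its replicate number beside it. Sulfur-deficient shoot 1 has the lowest score on the second component in both assays (-31.1 and -37.1).

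The first comparison asked which mRNAs differed between sulfur-deficient and control shoots. Most transcripts past the threshold were more abundant under deficiency. Sobic.001G493500.1, on chromosome 1, rose from 3.47 ± 0.726 to 151 ± 58.6 CPM (SD, n = 3 shoots), a log2 fold change of 5.43 (SE 0.477, edgeR adjusted p = 0.0295). Sobic.001G166401.1, also on chromosome 1, rose from 26.3 ± 5.79 to 432 ± 128 CPM (log2 fold change 4.04, SE 0.319, edgeR adjusted p = 0.0122). It has a coding length of 1071 bases and lies in ID order beside risen transcripts of 1032 and 1038 bases, so its value is uncertain if these share reads. Declines were smaller. Sobic.010G066601.1 on chromosome 10 fell from 5.72 ± 0.709 to 2.28 ± 0.646 CPM (log2 fold change -1.34, SE 0.217, edgeR adjusted p = 0.0226), and Sobic.003G436800.1 on chromosome 3 fell from 31.5 ± 7.25 to 15.7 ± 0.478 CPM (log2 fold change -1.01, SE 0.16, edgeR adjusted p = 0.0375).

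Of 20045 transcripts tested, 127 passed the edgeR threshold, 113 higher and 14 lower under deficiency. Among these, 42 rose and 3 fell at least 2-fold, 16 rose at least 4-fold and 3 at least 16-fold. The median absolute log2 fold change of the 127 was 0.77. Their groups did not overlap in any of the 127 cases, which held for 17.6% of all transcripts tested, against the 10% that chance gives. By level, 9 rose and 1 fell among 4951 transcripts under 4 CPM, 36 rose and 6 fell among 9140 between 4 and 32 CPM, 58 rose and 7 fell among 5461 in the next class, and 10 rose among the 493 most abundant. Called transcripts were spread over the 10 chromosomes, from 0.428% of those tested on chromosome 9 to 0.88% on chromosome 3, and no chromosome departed from the others (lowest adjusted p = 0.777, Fisher's exact test over 10 chromosomes).

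The count depended on each of the shoots: it was 35, 46 and 460 without control shoot 1, 2 or 3, and 508, 43 and 57 without sulfur-deficient shoot 1, 2 or 3, with 59.3% higher in the absence of control shoot 3 and 42.1% higher in the absence of deficient shoot 1, against 89% with all shoots. Every named transcript kept its direction in these 6 fits, but edgeR's adjusted p passed 0.05 in 5 of them for Sobic.001G493500.1 (0.0725 to 0.261, all but that without deficient shoot 1) and without control shoots 1 and 2 for Sobic.001G166401.1 (0.0988 and 0.0946). It also did so for Sobic.010G066601.1 without control shoots 1 and 2 and deficient shoots 2 and 3 (0.0781 to 0.125), and for Sobic.003G436800.1 without control shoot 2 and deficient shoots 2 and 3 (0.18 to 0.215). The sample descriptions number the control shoots 3, 1 and 7 and the deficient shoots 9, 13 and 15, without saying what the numbers mark. Numbers 1 and 3 hold control shoots alone, 13 and 15 deficient shoots alone, and 7 and 9 hold 1 of each, so that a fit with these pairs as a batch term rests on 1 shoot per treatment. That fit called 294 transcripts in RNA, 168 higher and 126 lower, and 74 of the 127 were among them. In it the log2 fold changes of Sobic.001G493500.1 and Sobic.001G166401.1 were 4.41 and 3.14, both past the threshold. Those of Sobic.010G066601.1 and Sobic.003G436800.1 were -1.1 and -1.15, against -1.34 and -1.01 without the batch term, and both missed the threshold. In RNA, numbers 1 and 3 (r = 0.9922) and numbers 13 and 15 (r = 0.9926) were the closest libraries, and in footprints 13 and 15 were not (r = 0.9731).

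The second comparison asked which transcripts differed in ribosome footprints. The 2 RNA transcripts named above as rising also rose in footprints, Sobic.001G493500.1 from 1.88 ± 0.425 to 67.7 ± 33.1 CPM (log2 fold change 5.17, SE 0.43, edgeR adjusted p = 0.00145) and Sobic.001G166401.1 from 17 ± 3.58 to 243 ± 103 CPM (log2 fold change 3.84, SE 0.329, edgeR adjusted p = 0.00145). Larger rises in the fit without a batch term were found for Sobic.004G258500.1 on chromosome 4, from 0.236 ± 0.115 to 17.1 ± 10.4 CPM (log2 fold change 6.10, SE 0.695, edgeR adjusted p = 0.00421), and for Sobic.005G003200.1 on chromosome 5, from 0.451 ± 0.11 to 22.6 ± 17.4 CPM (log2 fold change 5.65, SE 0.86, edgeR adjusted p = 0.029). The control footprint libraries of these 2 stood at 0.112 to 0.338 and 0.343 to 0.563 CPM, so the size of their rises rests on few control counts. In RNA these 2 had log2 fold changes of 6.43 and 4.48 that missed the threshold (edgeR adjusted p = 0.104 and 0.342). For Sobic.005G003200.1, sulfur-deficient shoot 1 stood at 2.95 CPM in footprints, against 28.9 and 35.9 in shoots 2 and 3. Footprints fell on Sobic.001G106600.1, from 151 ± 14.8 to 88.6 ± 7.61 CPM (log2 fold change -0.77, SE 0.128, edgeR adjusted p = 0.0486), and on Sobic.005G137000.1, chosen after its values were seen to complete the count of 2, from 3.89 ± 1.09 to 0.685 ± 0.179 CPM (log2 fold change -2.50, SE 0.381, edgeR adjusted p = 0.029). The deficient footprint libraries of Sobic.005G137000.1 stood at 0.481 to 0.819 CPM, so the size of its fall rests on few counts. Its RNA failed the filter and was not tested.

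**Figure D2:**
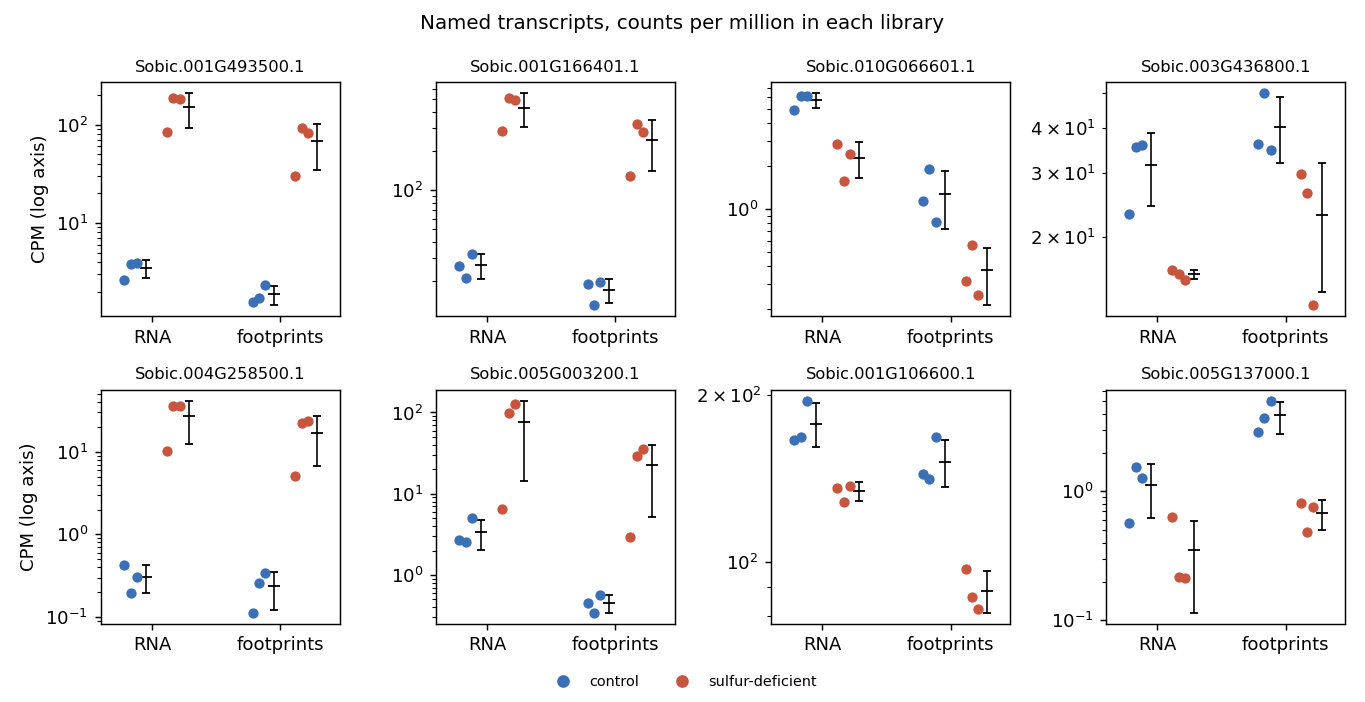
CPM (log axes) of the 8 named transcripts in each RNA and footprint library, with points for shoots and bars for the mean ± SD of 3 shoots. For Sobic.001G493500.1 the sulfur-deficient RNA libraries lie at 83.4 to 188 CPM and the control libraries at 2.63 to 3.92.

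Of 16514 transcripts tested in footprints, 37 passed the edgeR threshold, 35 higher and 2 lower. At least 2-fold changes numbered 32 higher and 1 lower, 14 rose at least 4-fold and 4 at least 16-fold. The median absolute log2 fold change was 1.83. All 37 had groups that did not overlap, a property of 10.9% of all transcripts tested and of 10% by chance. The number of calls was 18, 11 and 22 without control shoot 1, 2 or 3 and 70, 17 and 24 without sulfur-deficient shoot 1, 2 or 3, and 4 with the description numbers as a batch term. In that fit Sobic.004G258500.1 and Sobic.005G003200.1 had log2 fold changes of 3.86 and 2.36 and missed the threshold. The falling Sobic.001G106600.1 and Sobic.005G137000.1 missed it too, at -0.79 and -2.61, against -0.77 and -2.50 without the batch term. Sobic.001G493500.1 and Sobic.001G166401.1 had 3.66 and 2.71 and passed it. Sobic.004G258500.1 missed the threshold without any 1 of the control shoots (edgeR adjusted p = 0.136 to 0.175), Sobic.005G003200.1 without any shoot except deficient shoot 1 (0.0868 to 0.495), Sobic.001G106600.1 without any 1 of the 6 shoots (0.0579 to 0.237), and Sobic.005G137000.1 without control shoots 2 and 3 and deficient shoots 2 and 3 (0.098 to 0.207). Sobic.001G493500.1 missed it without control shoots 1 and 3 (0.0716 and 0.0861) and Sobic.001G166401.1 without control shoot 3 (0.0861). With no filter on low counts all 4 named rising transcripts missed it (edgeR adjusted p = 0.12 to 0.6), at log2 fold changes of 3.845 to 6.105. Both named falling transcripts passed it there (edgeR adjusted p = 0.00853 and 0.00293). Of the 70 footprint calls without deficient shoot 1, 49 were higher and 21 lower, or 70% higher, against 94.6% with all shoots. At this depth the median half-width of the 95% interval of a log2 fold change was 0.442 in footprints and 0.265 in RNA.

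Changes in footprints were then set beside those in mRNA. Across 16420 transcripts tested in both, the log2 fold changes had Pearson's r = 0.623 and Spearman's rho = 0.451, and 65.3% had the same sign. The orthogonal slope of footprints on RNA was 1.49 over these transcripts, and the noise of both assays enters it. For the 127 of these transcripts called in either assay, r was 0.970, rho was 0.923, the orthogonal slope was 1.01 and 98.4% had the same sign, on a set selected for large changes. Among transcripts tested in both, 108 rose in RNA and 35 in footprints, and 29 were shared, against 0.23 for independent lists. RNA and footprints of a shoot came from 1 powder, so part of this excess may reflect variation between shoots. Of the 79 that rose past the threshold in RNA alone, 77 also had a positive footprint fold change. The 6 called as rising in footprints alone had positive RNA fold changes. None of the 12 falling in RNA and the 1 falling in footprints were shared, against 0.000731 for independent lists. All 12 had a negative footprint fold change, and the 1 had a negative RNA fold change. Without sulfur-deficient shoot 3, r over all transcripts was 0.474.

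**Figure D3:**
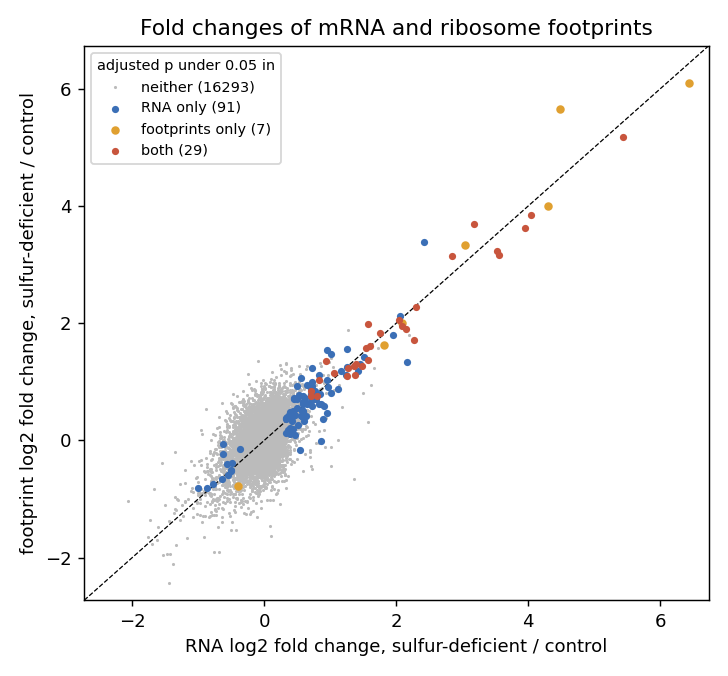
Log2 fold change (sulfur-deficient over control) in footprints against that in RNA for 16420 transcripts, coloured by the assay in which edgeR's adjusted p was under 0.05, with a dashed line of equal change. The 29 transcripts called in both lie along this line.

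The third comparison asked whether translational efficiency changed with sulfur supply. The edgeR interaction test called 0 of 16420 transcripts, with 410 at an unadjusted p under 0.05, which is 2.5% of those tested. DESeq2 called 0 (354 at an unadjusted p under 0.05), and limma on the ratio per shoot called 0 (553). With the shoot as a block edgeR called 0, with 598 (3.64%) at an unadjusted p under 0.05. If no efficiency changed, chance would put a share of 0.05 there, above both edgeR shares. The fit without the block also ignores that both libraries of a shoot came from 1 powder. Both edgeR fits may thus be too strict, and the 0 calls are weak evidence that efficiency did not change. In the edgeR fit without the shoot as a block, the median half-width of the 95% interval was 0.479 on the log2 scale. For 77.7% of transcripts that interval lay within a 2-fold change in either direction. The median SE was 0.223 in this fit and 0.201 with the shoot as a block.

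Sobic.001G493500.1 had a log2 change of -0.25 (95% interval -1.89 to 1.39) and Sobic.001G166401.1 one of -0.19 (-1.22 to 0.842). These intervals come from the fit without the shoot as a block; with it the changes were -0.31 (SE 0.237) and -0.25 (SE 0.153), at an edgeR adjusted p of 0.994. The highest change among the called transcripts was that of Sobic.005G003200.1, 1.19 (-4.11 to 6.5, edgeR adjusted p = 1), or 1.16 (SE 0.355, edgeR adjusted p = 0.994) with the block. Its efficiency did not overlap between groups (0.167 to 0.251 in control and 0.345 to 0.569 in deficient shoots). Such non-overlap held for 8.1% of all transcripts tested for efficiency, against the 10% that chance gives. The control footprints of Sobic.005G003200.1 stood at 0.343 to 0.563 CPM, so its control ratios rest on few counts and on the prior count. The log2 change of Sobic.001G106600.1 was -0.37 (-0.68 to -0.0568), with an interval below 0 but an edgeR adjusted p of 1. Over the 127 transcripts called in RNA or footprints, the median log2 change in efficiency was -0.022, with quartiles of -0.187 and 0.0988 and a range of -0.867 to 1.19. Of these, 5 had an unadjusted p under 0.05 in edgeR and 0 passed when adjusted over the list alone.

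Within control shoots, the ratio of footprints to mRNA differed far more between transcripts than between shoots. A count bias particular to a transcript would repeat in every shoot, and it was not separated from differences in efficiency. The log2 ratio had an SD of 0.995 across 16420 transcripts. Its 5th and 95th percentiles were -1.83 and 1.23, an 8.33-fold span. The median SD between the 3 control shoots was 0.184, and correlations between these shoots across transcripts were 0.903 to 0.941. Across transcripts, efficiency and coding length had a Spearman's rho of -0.0733 over the control mean, and of -0.108, -0.0943 and -0.0098 in control shoots 1, 2 and 3.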

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

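The label-number batch term, the left-out pairs, voom-limma and the limma ratio were chosen after seeing the data. For RNA (127 calls, 89% higher), counts were 259 with DESeq2 (77.2% higher), 200 with no filter, 45 with the 2-fold threshold, 71 with a spread shared over all 12 libraries, 294 with the label-number pairs as a batch term (57.1% higher) and 2294 without the shoots numbered 7 and 9 (55.6% higher). Leaving out 1 shoot gave 35 to 508. For footprints (37 calls), they were 95 with DESeq2, 17 with at least 50 counts in every group mean, 76 with the shared spread, 4 with the batch term and 77 without the shoots numbered 7 and 9. Leaving out 1 shoot gave 11 to 70. The 2294 was the highest of the 9 ways to leave out 1 control and 1 deficient shoot. The others gave 345, 410, 71, 42, 11, 10, 7 and 4 in RNA, and the 9 gave 0 to 104 in footprints. The 2-fold threshold and the stricter filter remove transcripts by construction. For the other shifts the cause was not tested, and the fit with the shared spread also tested fewer transcripts (16420, against 20045 in RNA). The replicate numbers shared by control and deficient shoots did not pair them (correlations of deviations -0.162, 0.188 and -0.0908 in RNA, -0.0181, -0.019 and 0.114 in footprints), and not every shoot correlated best with its own number. With the replicate block there were 95 RNA and 30 footprint calls. Translational efficiency had 0 calls under all 17 alternatives, DESeq2, limma and the shoot block included, with 229 to 1177 at an unadjusted p under 0.05 where 1 shoot was left out. Of these alternatives, the 2-fold threshold could give only 0, since it was applied to the main fit. The correlation of fold changes was 0.474 to 0.664 with 1 shoot left out, lowest without deficient shoot 3, and 0.970 for called transcripts. No named transcript reversed past the threshold, but RNA calls were lost under 5 of 17 alternatives for Sobic.001G493500.1, 2 of 17 for Sobic.001G166401.1, 6 of 15 for Sobic.010G066601.1 and 7 of 17 for Sobic.003G436800.1. Footprint calls were lost under 6 of 16 for Sobic.004G258500.1, 9 of 16 for Sobic.005G003200.1, 12 of 17 for Sobic.001G106600.1 and 8 of 15 for Sobic.005G137000.1. Not run were the gene list tests, since 0 IDs matched a description, and the fit without organelle genes, since no ID marks one. Recovery on simulated data was lower for footprints and efficiency than for RNA, and how much of this comes from depth was not tested.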

Other observations

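The tests of the label numbers, of the RNA library of deficient shoot 1 and of coding length were chosen after the values were seen. The splits of the shoots and the tests of neighbouring IDs were written before their results were seen.

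Sulfur-deficient shoot 1 lay closest to control shoot 3 in RNA and had smaller rises than deficient shoots 2 and 3. For the smaller rises, a fault of its RNA library alone is argued against, since over transcripts that rose in RNA its footprints were lower too (median log2 difference -0.2, against -0.0583 to 0.0565 for 95% of matched random lists). For the closeness this is not decided. In footprints deficient shoot 1 had r = 0.9788 with control shoot 1 and 0.9761 with control shoot 3. On the second footprint component the others scored 10.1 to 15.6, and control shoot 3 and deficient shoot 1 scored -12.5 and -37.1. These shoots carry description numbers 7 and 9, the nearest numbers across treatments, and in RNA numbers 1 and 3 (r = 0.9922) and 13 and 15 (r = 0.9926) were closer still; for 1268 transcripts called as rising and 1016 as falling between these other 4 RNA libraries, median log2 ratios of number 9 to number 7 were 0.0642 and -0.0819, outside matched random lists, but with 1 library per treatment a batch shared by numbers 7 and 9 cannot be told apart from a weaker response in shoot 1. Whether a trend with the label number may account for part of this was not decided. Over rises in RNA the ratio was 17.7% of that in the other 4 libraries against 68% to 127% for 7 other left-out pairs. The shoots were picked for lying close and carry the nearest numbers, which fixes that order beforehand. The lists differ too: the 1268 rises had a median log2 fold change of 0.363 in the other 4 libraries, those of the 7 pairs 0.779 to 1.74. How far this lowers the 17.7% was not tested. Over falls in RNA the ratio was 17.9% against -7.13% to 29.7% for 4 other pairs, with list medians of -0.459 against -0.656 to -1.17. Of 214 falls called without control shoot 1 and deficient shoot 1 only 38.8% had the same direction in that pair, as had 30.6% of 62 in footprints. Every control number lies below every deficient number, so treatment and order stay confounded.

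Risen RNA transcripts lay next to each other in ID order more often than random draws: 15 of 113 had another within 2 places, against a 95th percentile of 4 in 10000 draws (permutation p = 1e-04, the smallest they can give), so chance placement is argued against. Of the 8 neighbouring pairs, 75% had coding lengths within 10% of each other, compared with 11.4% of all tested neighbouring pairs. Sobic.001G166401.1 is in 2 of the 8 pairs, with 1071 bases beside 1032 and 1038. Reads shared between near-identical copies may therefore contribute, and so may copies that respond alike, and without sequences both stay open.

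Fold changes fell with coding length across transcripts (rho = -0.1 in RNA and -0.0902 in footprints), and the 113 risen RNA transcripts had a median coding length of 1038 bases, against 1083 to 1440 in matched random lists. The 35 risen in footprints had a median of 1146 bases, inside the matched range of 951 to 1572. Per-library correlations with length overlapped between groups in both assays, with a difference of -0.0352 in the footprint means, so they decide nothing about a length bias of the RNA-seq libraries, which stays open. The RNA values farthest from 0 were those of control shoot 3 (0.165) and deficient shoot 1 (-0.133). In footprints those of control shoot 3 (0.309) and deficient shoot 2 (-0.29) were farthest, and deficient shoot 1 stood at 0.0381. No biological explanation was tested.

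With 3 shoots against 3 there are 10 splits, too few for a share under 0.05. The real split gave 127 RNA calls, 1 of 10 as large, and the highest other split 36. That other split set control shoots 1 and 2 with deficient shoot 1 against the rest. For footprints 1 of 10 was as large, with 37 calls against 1. For translational efficiency the real count was 0, so 10 of 10 were as large by construction and the highest other gave 1. At an unadjusted p under 0.05 stood 2.5% of transcripts in the real split and 1.07% to 7.78% in the others. For the correlation of fold changes 1 of 10 was as large, 0.623 against 0.559.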
